A study of Sus scrofa domesticus with 11 samples.

How the data were processed

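Liver RNA was sequenced from Yorkshire piglets born preterm and kept on parenteral nutrition, collected at day of life 15. The labels assign 5 libraries to SEFA-6179, a compound known here by its code name and given at 48 mg/kg, and 6 libraries to MCT, the control, given at 3 ml/kg. MCT stands for medium-chain triglyceride, as known from the study. Sex, litter and sequencing batch are not given in the sources used here. The labels name each library as a separate sample of its group, and the series design text speaks of animals, so each library was taken as 1 animal.

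The deposited table holds 22029 genes, and each has at least 1 count in some library. Per the file headers, it gives for each library a raw read count per gene, and an FPKM value. A further deposited column per library is a normalized signal. Its ratio to the count is constant over the genes of a library, so it is the count divided by 1 size factor per library. The deposited FPKM values use a depth that follows those size factors. The authors also deposited group means of the normalized signal, a log2 fold change, a p-value and an adjusted p-value. The submitters' processing notes list HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.20.0 without saying which step each served. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and genes with near copies may have shared or lost reads.

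Gene symbols came from the table for 14022 genes and, by gene identifier, from a reference list for 779 more. The remaining 7228 genes have an identifier only. Total counts per library ran from 15974977 to 23416071. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom over genes was 45.7, between MCT replicates 2 and 4.

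The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 13671 genes. Libraries were scaled by the trimmed mean of M values (TMM). The quasi-likelihood test with robust dispersion estimates compared SEFA-6179 with MCT over all 11 libraries, two-sided, with Benjamini-Hochberg adjustment, a threshold of 0.05 and no minimum fold. Levels are CPM, counts scaled to the library total, after TMM scaling, as mean ± SD over libraries. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Before the data were examined, 40 gene lists were fixed for lipid, bile acid and energy metabolism, stress, inflammation, and the cell types a piece of liver can hold. The 39 lists with at least 3 tested members were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. List scores per library are the mean log2 CPM of the members minus their MCT mean.

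The rule for named genes was also set before the data were examined. It takes the 10 largest rises and the 10 largest falls among genes past the threshold with a symbol and a mean normalized count of at least 10, up to 4 genes past the threshold per list or otherwise the member with the smallest p, 17 genes named in advance, and the 5 genes with the smallest p. Some genes the rule names are not reported here. Genes named outside it are marked as chosen after their values were seen.

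The test was first run on simulated negative binomial counts with the means, library sizes and dispersions of these libraries, of which 13440 genes passed the filter. For the comparison of SEFA-6179 with MCT, edgeR recovered 58 of 100 genes changed by 1 on the log2 scale and 93 of 100 changed by 2, and 5 of its 156 calls were false. DESeq2 1.42.0 recovered 63 and 98, and 20 of its 181 calls were false. These simulated counts hold no correlation between genes.

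Alternatives fixed before the data were examined were DESeq2 size factors, no low-count filter, a mean count of at least 50, the DESeq2 Wald test, limma with library quality weights, a replicate block over replicates 1 to 5 of both groups, each library left out in turn, and the test without genes on X and Y. Other pseudocounts were planned for normalized values only and did not apply to counts. Chosen after the data were seen were a correction for gene length, the level of the Y-linked gene EIF1AY as a covariate, the test without MCT replicate 5 and SEFA-6179 replicate 4, and edgeR without robust estimation. Scores and permutation tests used Python 3.11.15 with scipy 1.17.1.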

Results

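The series profiled liver RNA of preterm Yorkshire piglets on parenteral nutrition, which is feeding by vein, to ask how hepatic transcription under SEFA-6179 differed from that under the MCT control. There were 5 SEFA-6179 libraries and 6 MCT libraries, all from day of life 15. Total counts ran from 16821201 to 19215097 per library with SEFA-6179 and from 15974977 to 23416071 with MCT. The 10 most abundant genes took between 17.4% and 26.6% of the counts of a library, and ALB, which encodes albumin, took between 4.04% and 11.6%.

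SEFA-6179 livers had more mRNA of CYP7A1, the rate-limiting enzyme of classical bile acid synthesis, and of ACAA2, the thiolase of the last step of mitochondrial beta-oxidation, and less of CDH1, which encodes E-cadherin. CYP7A1 was at 19.9 ± 14.1 CPM (SD, n = 5) with SEFA-6179 and 2.95 ± 1.05 CPM (SD, n = 6) with MCT, a 6.71-fold difference. ACAA2 was 3.18-fold higher and CDH1 1.95-fold lower. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 30 of 13671 genes changed, 16 higher and 14 lower in SEFA-6179. In 27 of these 30 genes every SEFA-6179 library lay beyond every MCT library, which genes picked for a low p in the same libraries tend to show. Over all tested genes 204 showed such a separation, where chance gives 0.433% of genes, or 59.2, on average. How far that number varies by chance was not computed, and genes do not vary independently.

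The number of calls rested on single libraries: it was 0 without SEFA-6179 replicate 5 and 0 without MCT replicate 4 (edgeR; 1184 and 1258 genes at an unadjusted p below 0.05, and 165 and 167 calls by DESeq2), 1 without MCT replicate 1, 9 without SEFA-6179 replicate 1, 9 without MCT replicate 2, 16 without MCT replicate 3 and 53 without SEFA-6179 replicate 3. Each of the 30 calls was kept in 1 to 8 of the 11 tests that left out 1 library. CYP7A1 passed only without SEFA-6179 replicate 2 or 3, CDH1 only without SEFA-6179 replicate 4 or MCT replicate 6, ACADL only without SEFA-6179 replicate 3 or MCT replicate 6, and ACAA2 only without SEFA-6179 replicate 3 or 4 or MCT replicate 5 or 6. Their highest adjusted p were 0.149, 0.158, 0.124 and 0.106, and none of the 4 changed sign, with log2 fold changes of at least 2.34, 0.89, 0.79 and 1.48 in size. With all libraries DESeq2 called 276 genes and limma with library weights 78, both sets including the 30, while 6 calls were left with the level of EIF1AY as a covariate and 1, not among the 30, without MCT replicate 5 and SEFA-6179 replicate 4.

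The authors' deposited table held 255 genes with an adjusted p below 0.05, 116 higher and 139 lower in SEFA-6179. The edgeR test covered 249 of the genes called in the authors' deposited table, and all 249 had the same sign. All 30 edgeR calls were among them. So were some genes named below that did not pass by edgeR, such as PLIN2, KLB, CD24, EGR1, APOA2, PCK1 and NDUFA5.

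Of 18 tested genes of mitochondrial beta-oxidation 16 had a log2 fold change above 0, and the list was higher in SEFA-6179 by camera (median log2 fold change 0.26, adjusted p = 2.7e-05; adjusted p = 0.733 with an estimated correlation). ACAA2 rose from 128 ± 59.0 CPM (SD, n = 6) to 405 ± 110 CPM (SD, n = 5), with a log2 fold change of 1.67 ± 0.29 (SE) and an adjusted p of 0.0319 by edgeR. ACADL, the long-chain acyl-CoA dehydrogenase, rose from 58.9 ± 11.3 to 106 ± 13.2 CPM (edgeR adjusted p = 0.0398). These 2 members passed the threshold over all genes and 5 passed when adjusted over the list alone. Over libraries the score of the list was 0.348 higher with SEFA-6179 (exact permutation p = 0.0260). Adjusted over 11 such tests, chosen after the values were seen, that p was 0.0952 and did not pass. Of 18 tested genes of peroxisomal lipid oxidation 14 lay above 0 (camera adjusted p = 0.000864; adjusted p = 0.733 with an estimated correlation). Its 1 member past the threshold was CROT, which transfers medium-chain acyl groups to carnitine in peroxisomes, at 189 ± 39.9 against 89.8 ± 14.7 CPM (edgeR adjusted p = 0.0273). Adjusted over the list alone, 2 members passed. CROT overlaps a gene on the opposite strand with a mean count of 3453, and the strand setting of the counting is not given in the sources used here.

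The wider set of PPARA targets was not called (25 tested members, 16 above 0, camera adjusted p = 0.161), though it was called higher without SEFA-6179 replicate 3 (adjusted p = 0.0186) and with the EIF1AY covariate (adjusted p = 0.0433). Over all genes 1 member, ACADL, passed, and adjusted over the list alone 4 were higher and 1 lower. Several targets named in advance did not pass by edgeR. The log2 fold change of CPT1A, the gatekeeper of mitochondrial fatty acid entry, was 0.14 ± 0.27 (SE). That of PDK4, which restrains pyruvate oxidation, was -0.0014 ± 0.18, and that of ANGPTL4 was -0.11 ± 0.19. FGF21 had a log2 fold change of -0.53 ± 0.35. PLIN2, a coat protein of lipid droplets, was at 62.9 ± 19.1 CPM with SEFA-6179 and 153 ± 51.3 CPM with MCT. Its adjusted p was 0.0692 by edgeR and 0.000744 by DESeq2, the lowest over the alternatives, of which the highest was 0.185, and 4 of 5 SEFA-6179 libraries lay below all MCT libraries.

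All 11 tested genes of bile acid synthesis had a log2 fold change above 0, with a median of 0.35 (camera adjusted p = 0.000509; adjusted p = 0.667 with an estimated correlation). CYP7A1 (log2 fold change 2.75 ± 0.49 SE, edgeR adjusted p = 0.0478) passed over all genes, and 2 members passed when adjusted over the list alone. All 5 SEFA-6179 libraries lay above all MCT libraries for CYP7A1, with 39.5 CPM in replicate 4 and 4.91 CPM in replicate 3, against at most 4.16 CPM with MCT. CYP8B1, the sterol 12-alpha-hydroxylase, was at 6.25 ± 5.86 against 0.467 ± 0.540 CPM and did not pass (edgeR adjusted p = 0.218). The transporters of bile and organic anions were not called (2 of 11 tested members above 0, camera adjusted p = 0.163), but were called lower without MCT replicate 5 (adjusted p = 0.0260). ABCB11, the bile salt export pump, had a log2 fold change of -0.38 ± 0.28 (SE). KLB, a co-receptor of fibroblast growth factors 19 and 21, was at 61.7 ± 49.9 against 17.3 ± 6.64 CPM (edgeR adjusted p = 0.204).

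**Figure D1:**
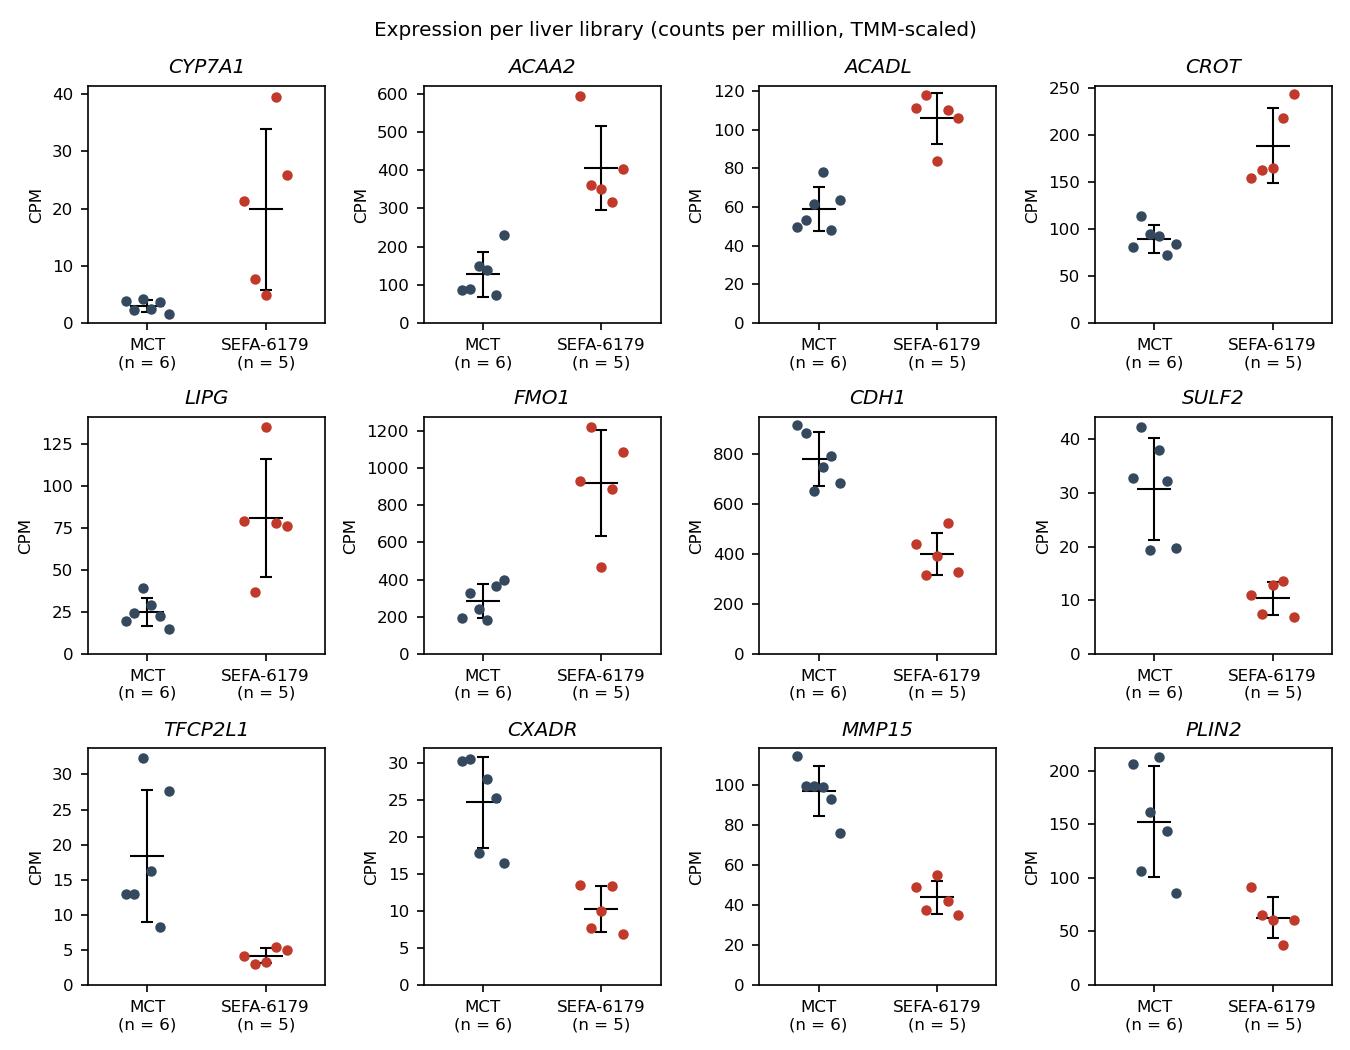
CPM (vertical axis, linear, from 0) of 12 genes in each of 6 MCT and 5 SEFA-6179 liver libraries; each point is a library, the dash is the group mean and the bar its SD. PLIN2 did not pass the threshold over all genes, and the CYP7A1 values of SEFA-6179 spread from 4.91 to 39.5 CPM.

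Other genes that rose were LIPG, an endothelial-type lipase (81.2 ± 35.2 against 25.1 ± 8.59 CPM), and the flavin monooxygenase FMO1 (919 ± 284 against 284 ± 91.3 CPM). DHRS4, a short-chain dehydrogenase, was at 1157 ± 382 against 427 ± 113 CPM, and MCTP1 at 9.88 ± 1.82 against 2.67 ± 0.882 CPM. HPRT1, of purine salvage, rose 2.00-fold, and GLRX5, a mitochondrial glutaredoxin, 1.98-fold. RPS29, a ribosomal protein gene, was 2.77-fold higher. RPS29 and DHRS4 have near copies in some mammalian genomes, and FMO1 has related genes. Whether reads were shared with such genes was not tested, so these counts may be uncertain. The edgeR adjusted p of these 7 genes lay between 0.0239 and 0.0478. The unnamed gene ENSSSCG00000017608, on chromosome 12 from 32043861 to 32156018, was 4.09-fold higher, and ENSSSCG00000013150 was 2.00-fold higher. Coordinates are those of the deposited table.

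Of the 14 genes that fell, CDH1 (chromosome 6, 18075480 to 18155986) went from 779 ± 107 CPM (SD, n = 6) to 400 ± 84.6 CPM (SD, n = 5), with an edgeR adjusted p of 0.0478. CXADR, an epithelial junction protein, was at 10.3 ± 3.08 against 24.7 ± 6.16 CPM, and TFCP2L1, a transcription factor of epithelia, at 4.15 ± 1.07 against 18.4 ± 9.46 CPM. SULF2, an extracellular sulfatase, was 2.96-fold lower and MMP15, a membrane-bound metalloproteinase, 2.21-fold lower. GALNT7, TENT5C, CRYBG2 and DISP3 were between 2.02-fold and 2.40-fold lower. CLGN was at 0.332 ± 0.119 against 2.27 ± 0.947 CPM. MMP15 overlaps CFAP20 on the opposite strand, which has a mean count of 1360.

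Of 13 tested cholangiocyte markers, genes of bile duct cells, 12 had a log2 fold change below 0, with a median of -0.83 (camera adjusted p = 9.99e-06; adjusted p = 0.667 with an estimated correlation). None passed over all genes by edgeR, and 5 passed when adjusted over the list alone. Over libraries the cholangiocyte score differed by -0.772 between SEFA-6179 and MCT (exact permutation p = 0.0173). Adjusted over 11 such tests, chosen after the values were seen, its p was 0.0952 and did not pass. CD24 was nearest to the threshold, at 3.39 ± 1.19 against 8.43 ± 1.97 CPM (edgeR adjusted p = 0.0539), and KRT7 was at 3.64 ± 1.83 against 7.27 ± 2.41 CPM (edgeR adjusted p = 0.274). KRT19 was not among the genes tested. Endothelial markers went the other way, with 16 of 17 above 0 and a median of 0.36 (camera adjusted p = 0.000509; adjusted p = 0.733 with an estimated correlation), and no member passed by edgeR. Hepatocyte markers were not called (10 of 17 above 0, camera adjusted p = 0.931).

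Stellate cell and fibrosis genes lay mostly below 0 (23 of 28, camera adjusted p = 0.0146), and so did cell cycle genes (26 of 31, camera adjusted p = 0.00098). With an estimated correlation the adjusted p of both was 0.733. No member of either list passed by edgeR. COL1A1 was at 102 ± 40.1 against 159 ± 51.9 CPM and COL1A2 at 83.8 ± 16.6 against 135 ± 41.1 CPM. The stellate cell call was lost without SEFA-6179 replicate 2 or 3, and the cell cycle call without SEFA-6179 replicate 1, with adjusted p of at most 0.0761 and 0.0779.

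Nuclear genes of oxidative phosphorylation lay above 0 in 45 of 48 tested cases (median log2 fold change 0.27, camera adjusted p = 2.33e-08; adjusted p = 0.733 with an estimated correlation), and none passed by edgeR. The lowest p of the list was that of NDUFA5, a subunit of complex I, at 33.3 ± 4.54 against 21.7 ± 4.43 CPM (edgeR adjusted p = 0.139). Genes of the mitochondrial genome were called higher (10 of 13 above 0, camera adjusted p = 0.00639; adjusted p = 0.733 with an estimated correlation) and cytosolic ribosomal proteins too (28 of 45 above 0, camera adjusted p = 0.0424; adjusted p = 0.865 with an estimated correlation). With a correction for gene length both calls ended, at adjusted p of 0.287, with a median of -0.035, and 0.379, with a median of 0.057. The first was also lost without SEFA-6179 replicate 5 or MCT replicate 3 or 5 (adjusted p of at most 0.133), and the second without SEFA-6179 replicate 2, 4 or 5 or MCT replicate 1, 2 or 3 (at most 0.998).

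Camera also called 6 further lists. Cholesterol synthesis (20 of 25 above 0, adjusted p = 0.043), the urea cycle and amino acid breakdown (13 of 17, adjusted p = 0.0159), acute phase proteins (10 of 10, adjusted p = 0.00613) and T and NK cell markers (13 of 16, adjusted p = 0.0343) were higher. Interferon response genes (25 of 26 below 0, adjusted p = 0.0415) and immediate early genes (8 of 14 below 0, adjusted p = 0.0300) were lower. With an estimated correlation the adjusted p was 0.85 for cholesterol synthesis, 0.865 for the interferon response and 0.733 for the other 4. No member of these 6 lists passed by edgeR. EGR1, an immediate early gene, was at 21.2 ± 9.66 against 55.2 ± 14.3 CPM (edgeR adjusted p = 0.0752). The interferon call was kept in 5 of the 11 tests that left out 1 library, and lost without SEFA-6179 replicate 2, 3 or 5 or MCT replicate 3, 5 or 6, with the highest adjusted p, 0.937, without MCT replicate 5. Without that library the median log2 fold change was -0.12, against -1.15 with all libraries, and camera's direction turned. The acute phase call was lost without SEFA-6179 replicate 3 alone (adjusted p = 0.124). The call of cholesterol synthesis was lost without SEFA-6179 replicate 1, 2 or 4 or MCT replicate 3, 4 or 6 (adjusted p of at most 0.55), that of the urea cycle without SEFA-6179 replicate 4 or 5 or MCT replicate 5 (at most 0.336), that of T and NK cells without SEFA-6179 replicate 1 or 3 or MCT replicate 1, 3 or 6 (at most 0.278), and that of immediate early genes without SEFA-6179 replicate 2 or 5 or MCT replicate 3, 5 or 6 (at most 0.561).

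In total camera called 16 of 39 lists with its preset correlation, 11 higher and 5 lower. With an estimated correlation it called 0, with 2 lists at an unadjusted p below 0.05, and fry called 0, with 4. The calls of mitochondrial beta-oxidation, peroxisomal lipid oxidation, bile acid synthesis, cholangiocyte, endothelial and oxidative phosphorylation genes held in all 11 tests that left out 1 library. The other 23 lists were not called, with camera adjusted p from 0.111 for lipoproteins to 0.996 for fatty acid synthesis. Among these, macrophage markers had a median of 0.34 (13 of 16 above 0), while camera placed them lower (adjusted p = 0.971) but called them higher without SEFA-6179 replicate 4 (adjusted p = 0.000224). Lipoproteins were called higher without SEFA-6179 replicate 3 or MCT replicate 1 (adjusted p = 0.00292 and 0.0372). The median and the camera direction also differed in sign for erythroid, inflammatory mediator, lipid droplet, heat shock and p53 target genes. FASN had a log2 fold change of -0.37 ± 0.65 (SE) and SCD one of 0.09 ± 0.97. AFP, a fetal liver gene that overlaps ALB on the same strand in the deposited table, had one of -0.78 ± 0.59, and GPR84, which the deposited table marks as a pseudogene, with a mean normalized count of 17.2, one of 0.42 ± 0.75.

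**Figure D2:**
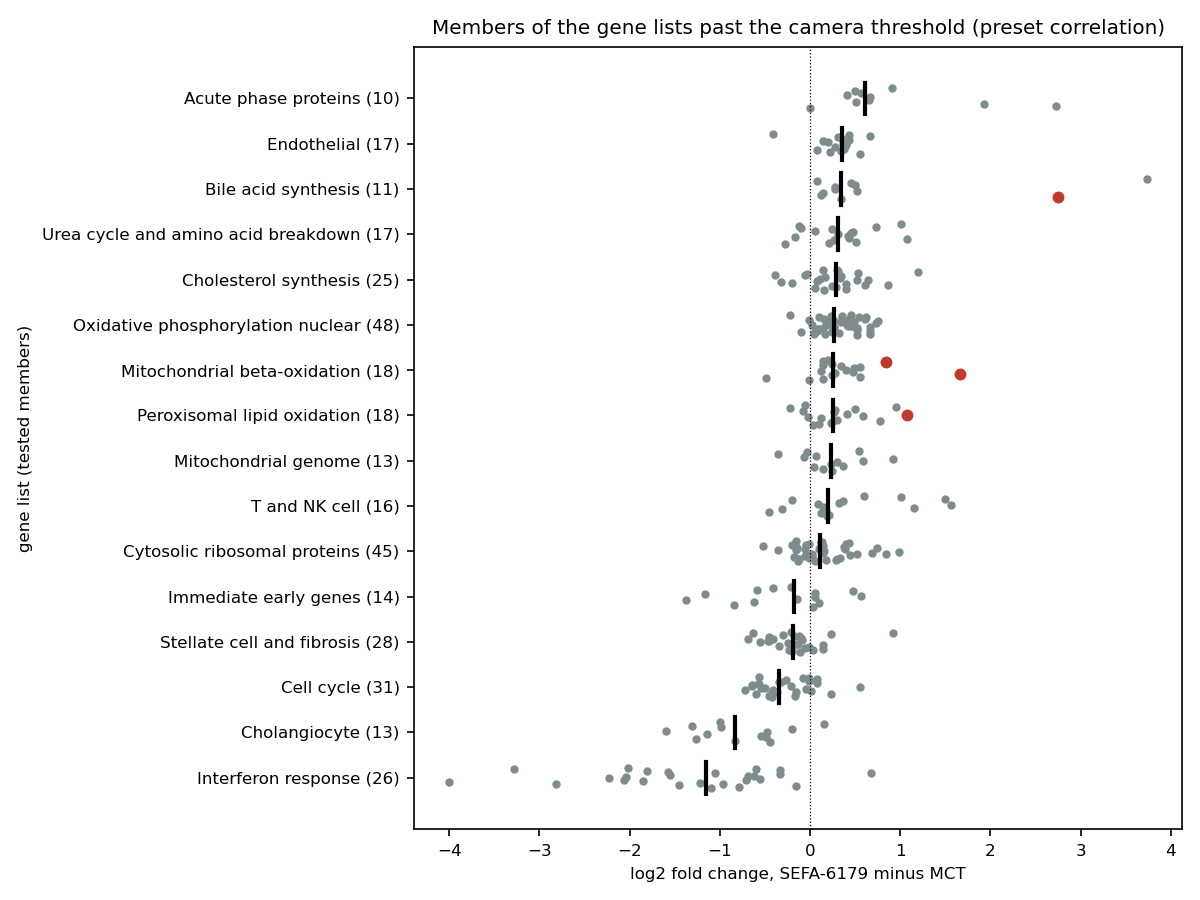
Log2 fold change (horizontal axis, SEFA-6179 minus MCT) of each tested member of the 16 gene lists past the camera threshold with a preset correlation; grey points did not pass over all genes, red points did, and black bars are list medians. The median of the cholangiocyte list is -0.83 and that of bile acid synthesis 0.35.

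**Figure D3:**
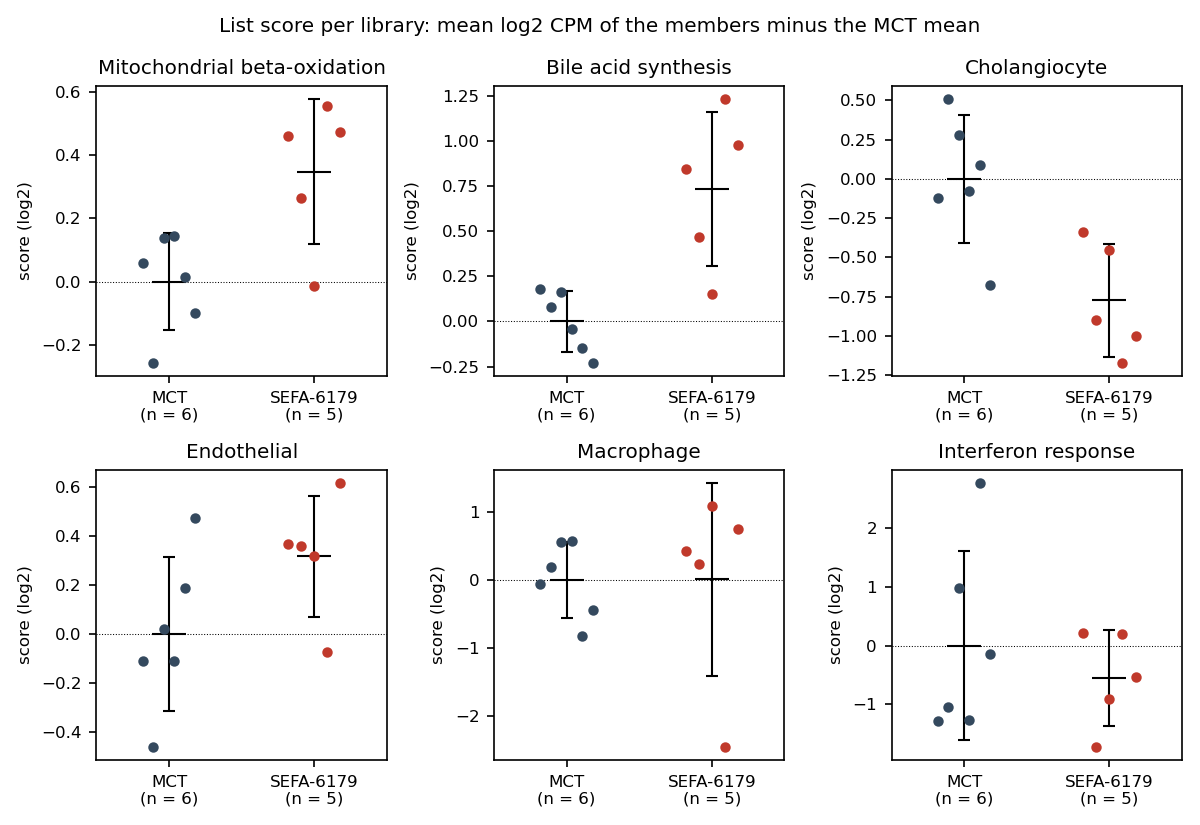
Score per library (vertical axis, mean log2 CPM of the members minus their MCT mean) of 6 gene lists in 6 MCT and 5 SEFA-6179 libraries; points are libraries, the dash is the group mean and the bar its SD. The macrophage score of SEFA-6179 replicate 4 is -2.46 and the interferon score of MCT replicate 5 is 2.77.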

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

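All tests of explanations in this part were chosen after the values were seen, except the count of splits of the samples, which was set before it was computed. Of the 228 groups covered here, 11 held a library far from the rest of its group, and chance gives about 11.4.

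In none of 99 other splits of the 11 libraries into 5 and 6 did edgeR call as many genes as in the real one: 1 of 100 splits, the real one with 30 calls, reached that number, and the highest other split gave 9. Chance is thus argued against for the number of genes, though 1 of 100 is the smallest share these splits can give. An imbalance of sex or litter between the groups is not tested by them. EIF1AY, a Y-linked gene chosen after its values were seen, was detected in SEFA-6179 replicates 1 and 4 and MCT replicates 1, 3, 4 and 6. It was 0 in the other libraries, so the groups differed in the share of libraries with it. With its level as a covariate, edgeR kept 6 of the 30 calls. Chance is not argued against for the number of gene lists: 16 of 100 splits gave at least the 16 lists of the real one, and the highest other split gave 20.

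MCT replicate 5 stood apart on the first principal component, at 83.1 against -15.1 to -3.03 in the other MCT libraries, a component with 19.6% of the variance. Its OASL level was 47.4 CPM, against at most 1.59 CPM in the other MCT libraries, and its heat shock score was 0.93 against at most 0.10. The macrophage score of SEFA-6179 replicate 4 was -2.46, against 0.23 to 1.10 in the other SEFA-6179 libraries, and its VCAM1 level was 20.4 CPM against at least 44.8 CPM.

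Both libraries had a low macrophage score, -2.46 in SEFA-6179 replicate 4 and -0.83 in MCT replicate 5, against -0.44 or more in the other 9 libraries. Not every member of the list was low. CD14 was at 778 CPM in SEFA-6179 replicate 4 and 1461 CPM in MCT replicate 5, against 726 to 1488 CPM in the other 9. The next marker, which is not in the list, was chosen after its values were seen. CLEC4F, a Kupffer cell lectin, was at 0.953 CPM in SEFA-6179 replicate 4 and 0.112 CPM in MCT replicate 5, against 43.6 CPM or more in the other 9 libraries. A smaller share of all cells other than hepatocytes is argued against, since in both libraries (2 of 2) the endothelial score lay inside the range of the other 9 while the macrophage score lay below it. Low depth is argued against too, since total count and number of detected genes lay inside the range of the other 9 in 2 of 2. ISG15, an interferon-induced gene also chosen after its values were seen, was at 5051 CPM in MCT replicate 5 and 291 CPM in SEFA-6179 replicate 4. Whether macrophage markers fall where interferon genes are high stays open. Over 11 libraries Pearson's r was -0.371 (permutation p = 0.239, adjusted 0.479) and Spearman's rho -0.236 (permutation p = 0.486, adjusted 0.486). Without MCT replicates 5 and 3, r was -0.474. Apart from this relation no biological explanation was tested, as the labels give no group that parts these animals.

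The acute phase score of SEFA-6179 replicate 3 was 2.12, against 0.25 to 0.50 in the other SEFA-6179 libraries. SEFA-6179 replicate 2 had CYP3A29 at 619 CPM against at least 2071 CPM, PDK4 at 356 CPM against at most 262 CPM, and GP2 at 0 CPM against at least 0.246 CPM. IGF2BP1 was at 1.85 CPM in SEFA-6179 replicate 5 against at least 3.93 CPM. CLGN was at 0.496 CPM in MCT replicate 1 against at least 1.95 CPM in the other MCT libraries.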

How the results depend on the processing

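The length correction, the EIF1AY covariate, the omission of both MCT replicate 5 and SEFA-6179 replicate 4, and edgeR without robust estimation were chosen after the data were seen. The 30 calls (16 higher, 14 lower) became 276 (125 and 151) with the DESeq2 Wald test and 78 (35 and 43) with limma and library weights, both holding all 30. They became 6 (5 and 1) with the EIF1AY covariate and 1 (0 and 1) without MCT replicate 5 and SEFA-6179 replicate 4. With no filter there were 44 calls, 28 of them shared, and DESeq2 size factors gave the same 30. A mean count of at least 50 gave 31, no genes on X and Y 29, the length correction 32 and no robust estimation 26, with 29, 29, 30 and 26 shared. Leaving out 1 library gave 0 to 53 calls, 0 to 33 higher and 0 to 21 lower, and none of the 30 genes changed sign. Fewer samples lower the power of these tests, but the cause of each shift was not tested.

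No label says that replicate numbers pair the samples, and same-numbered libraries showed little shared deviation, with correlations of -0.058, 0.060, 0.202, -0.149 and -0.004. These correlations cannot exclude a pairing by litter or batch, which are not given. The fit with a replicate block, which also leaves out MCT replicate 6 as it has no partner, gave 8 calls, 3 higher and 5 lower, 4 of them shared with the 30; without MCT replicate 6 and with no block there were 40.

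The 16 lists became 10 with library weights, 0 with an estimated correlation and 0 with fry, and 10 to 15 without 1 library. Some calls ended with the median log2 fold change about as large (median, adjusted p): T and NK cells (median 0.20 with a call) at a mean count of at least 50 (0.19, 0.771), the length correction (0.19, 0.0555) and the EIF1AY covariate (0.24, 0.130), and with that covariate cholesterol synthesis (0.29 in both, 0.111) and immediate early genes (-0.17 from -0.18, 0.0944). Whether gene length or sex weakened these calls was not tested. The medians do not settle it, since camera does not test the median. The covariate also ended cytosolic ribosomal proteins (0.049 from 0.11, 0.374), the test without X and Y cholesterol synthesis (0.24, 0.103), and the block cholesterol synthesis (0.16, 0.150), T and NK cells (0.13, 0.208) and immediate early genes (-0.17, 0.118). Without MCT replicate 5 and SEFA-6179 replicate 4 the urea cycle (0.22 from 0.31, 0.669), interferon (-0.39 from -1.15, 0.504), cholesterol (0.19, 0.0870), mitochondrial genome (0.077 from 0.23, 0.0870) and immediate early (-0.042, 0.0726) calls ended. With library weights 6 calls ended, the interferon (adjusted p = 0.946) and immediate early (-0.027, 0.325) ones among them. Camera called B and plasma cell markers higher with no filter (adjusted p = 0.0328) and erythroid markers higher with the block (adjusted p = 0.0365). The median log2 fold change of the macrophage list ranged from 0.11 to 0.60 without 1 library, was -0.14 with library weights, and was 0.48 without MCT replicate 5 and SEFA-6179 replicate 4; camera called it higher without SEFA-6179 replicate 4 and without both libraries (adjusted p = 0.000224 and 0.00173, and from 0.281 to 0.999 under the other alternatives). Camera turned the direction of the interferon list without MCT replicate 5 (median -0.12, from -1.43 over the omissions) and with library weights (median -0.0013), and of the cytosolic ribosomal list without MCT replicate 3 (median 0.023, up to 0.18 over the omissions); neither list was past the threshold there. The cause was not tested. Genes near 1 CPM, such as CLGN, rest on few reads per library.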

Other observations

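The tests of cell shares below were chosen after the lists' values were seen, and so was the correction for gene length; the comparison with matched random lists was set before it was computed. LIPG and ACAA2, both higher in SEFA-6179, are near each other on chromosome 1 in the deposited table (99081938 to 99110876 and 99280800 to 99332381), and FMO1 and FMO4 on chromosome 9 (63812103 to 63895077 and 63908867 to 63934983). FMO4, chosen after its values were seen, was 42.0 CPM on average with SEFA-6179 and 25.8 CPM with MCT. EIF1AY, a Y-linked gene chosen after its values were seen, was between 19.2 and 24.5 CPM in SEFA-6179 replicates 1 and 4 and MCT replicates 1, 3, 4 and 6, and 0 in the other libraries. PCK1, of gluconeogenesis, was at 3011 ± 344 CPM (SD, n = 5) against 1865 ± 404 CPM (SD, n = 6), and APOA2 at 1043 ± 456 against 467 ± 124 CPM. Neither passed by edgeR, with adjusted p of 0.188 and 0.123.

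Short genes lay slightly higher in SEFA-6179, with a median log2 fold change of 0.06 in the shortest of 5 groups of genes by length and -0.02 in the longest. The oxidative phosphorylation median of 0.27 lay at percentile 99.97 of 10000 random lists matched on length and expression, whose middle value was 0.074. It was 0.23 after the length correction. Gene length is thus argued against as the whole account of this median in these libraries. The matched genes were drawn separately, without the correlation between members of a real list. Their spread may be too narrow, and the percentile does not measure the spread between animals. For beta-oxidation the matched lists did not exclude gene length: percentile 95.93 lay below the bound set beforehand, so by that rule length remained a possible cause. The matched lists also match expression. With the length trend removed, a correction chosen after the data were seen, the median was 0.27 against 0.26 and the list stayed past the threshold. For cytosolic ribosomal proteins length may account for the difference: percentile 16.45, and a median of 0.06 after the correction against 0.11. Whether a larger share of hepatocyte RNA adds to the beta-oxidation levels stays open. It would lower the markers of other cell types. The endothelial median was 0.358, with a bootstrap interval over genes of 0.22 to 0.40, but over libraries the endothelial score was 0.318 higher with an exact permutation p of 0.0996 (adjusted over 11 such tests, 0.183). Stellate cell genes went the way this explanation predicts, with 23 of 28 below 0 and a median of -0.19, but over libraries their score differed by -0.155 with an exact permutation p of 0.229 (adjusted 0.333). T and NK cell markers went the other way (13 of 16 above 0, median 0.20), and their score was 0.513 higher with an exact permutation p of 0.242 (adjusted 0.333). By the same exact permutation test the hepatocyte score differed by -0.0076 (p = 0.974, adjusted 0.987), the beta-oxidation minus the hepatocyte score was 0.355 higher (p = 0.0736, adjusted 0.183), and the beta-oxidation minus the endothelial score 0.030 higher (p = 0.896, adjusted 0.987), so the oxidation score was not shown to rise more than either. A response of oxidation genes to SEFA-6179 stays a hypothesis.

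A larger share of hepatocyte RNA, as the whole account of the fall of cholangiocyte markers, would lower endothelial markers alike. The medians of the 2 lists differed by 1.186, with a bootstrap interval over genes of 0.77 to 1.52, which does not measure the spread between animals. Per library, the endothelial minus the cholangiocyte score was 1.09 higher with SEFA-6179 (exact permutation test over 462 splits, two-sided, p = 0.0173; 0.0952 when adjusted over all 11 such tests of list scores, the other 10 of which were run after it). With 12 of 13 tested markers below 0, fewer bile duct cells in the sampled pieces and lower expression per cell cannot be told apart, since bulk RNA holds no count of cells. Either may follow from the treatment or from where the pieces were taken.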
